A study of Mus musculus and Homo sapiens with 59 samples.

How the data were processed

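Polyadenylated RNA of 59 libraries was used: 35 of NIH3T3, 16 of LLC, 4 of HT29 and 4 of BxPC3 cells, in 30 groups named by line, construct or siRNA, medium and treatment in the labels. The deposited values are TPM, with 19407 rows for mouse and 22192 for human cells, and the unit was inferred from the values, whose totals per library lay between 999910 and 999989 for mouse libraries. The authors quantified transcripts with Salmon and named the genome builds mm10 and hg19, per the submitters' processing notes. The version, index, trimming and the way transcripts were summed to genes are not given in the sources used here. TPM keep no sequencing depth, so neither the depth of a library nor the counting error of a gene can be given, and the only measure of precision is the spread between the libraries of a group. Mouse transcript lengths, GC contents and positions came from the GENCODE vM21 annotation of mm10, by gene symbol, and no human annotation was used.

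Groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The design planned a count-based test and named limma as the fallback for a normalized unit, and the fallback was used because the values are TPM. Each comparison was fitted on log2(TPM + 1) with limma 3.58.1 (trend) in R 4.3.3, in a single model per line over all its groups (HT29 and BxPC3 in a joint model), without a replicate block. A gene was tested where at least 2 libraries of the comparison held 1 TPM or more, and passed at a Benjamini-Hochberg adjusted p under 0.05 within the comparison. There were 23 comparisons: 15 of treated with untreated cells, 6 interactions that test whether 2 responses differ, and 2 of untreated cells. Each compared treated with its own untreated libraries, so that no control was shared between treatment comparisons, while interactions and comparisons of untreated cells use libraries of those comparisons again. The siPKC group given AP20187 has 1 library and takes its variance from the other groups.

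The 19 gene lists were cytokines and chemokines, immediate early genes, NF-kB targets, ERK feedback, calcium, NFAT and CREB responsive genes, SRF and YAP targets, the unfolded protein and integrated stress response, heat shock, metal and oxidative stress, interferon stimulated genes, cholesterol synthesis and uptake, p53 targets, membrane repair and ESCRT, protein kinase C, mitochondrially encoded genes, ribosomal proteins, and macrophage, epithelial and fibroblast markers. Lists were tested with limma's camera (preset correlation 0.01, and an estimated correlation beside it), adjusted over lists within a comparison, and members were also adjusted over the list alone. Camera compares a list with the other genes, so a list can be called upward while its median is below 0.

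The genes named are a selection from a fixed rule. Among genes past the threshold whose treated libraries all lay on the same side of all untreated ones and whose mean was at least 5 TPM in the higher group, it takes the 12 largest rises and 6 largest falls. It adds up to 4 members of each list by smallest p, a fixed set of chemokine and early response genes in every comparison, Rela, protein kinase C genes, Gsdmd and Mlkl where they are targets or constructs, and the 6 largest differences each way for interactions and comparisons of untreated cells. Within what the rule allows, the selection was made after the values were seen, and several genes whose direction depends on the scaling were passed over. Genes higher in all comparisons of a set were counted beside the number expected of independent lists.

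The fit was tested on simulated data with 200 changed genes, at folds of 1.5, 2 and 4. It recovered 89.6%, 97.0% and 100% of them in the simulation of NIH3T3 MLKL cells (11585 genes, 17 false calls), 94.0%, 100% and 98.5% for LLC GSDMD cells (10916 genes, 14 false calls) and 79.1%, 94.0% and 100% for HT29 cells (12100 genes, 8 false calls). False calls made up 8.17%, 6.70% and 4.21% of all calls, above the nominal 5% in the mouse lines. Alternatives tried were a pseudocount of 0.1, quantile normalization, no filter, only the libraries of the comparison, a replicate block and leaving out each library. Median centring, removal of 446 mouse and 721 human small RNA and ribosomal RNA rows, removal of the trend with transcript length and the use of parental untreated libraries were added after the data were seen. The values were read with the R package data.table (1.17.8) and figures drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.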

Results

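Polyadenylated RNA was measured in 59 libraries of cultured cells whose plasma membrane was permeabilized by a pore-forming protein or by a detergent. NIH3T3 mouse fibroblasts gave 35 libraries and LLC cells, a mouse lung carcinoma line, gave 16. These cells carried no construct (parental), an amino-terminal fragment of human MLKL fused to a dimerizable domain, or an amino-terminal fragment of mouse GSDMD fused to a hormone-binding domain. MLKL and GSDMD are the proteins that open the plasma membrane in necroptosis and pyroptosis. The dimerizer AP20187 (100 nM, 1 h) was added to MLKL cells and to parental NIH3T3 cells, and 4OHT (tamoxifen metabolite, 50 nM, 2.5 h) to GSDMD cells and to parental LLC cells. Digitonin, a detergent that binds membrane cholesterol, was given at 55 µg/mL for 3 h to NIH3T3 and LLC cells, and at 40 µg/mL for 2 h to the human lines HT29 (colorectal carcinoma) and BxPC3 (pancreatic carcinoma), which gave 4 libraries each. NIH3T3 MLKL cells were also stimulated in calcium-free medium, after a control siRNA (siCTR) or an siRNA named siPKC, and in a p65 knockout (p65ko) or its control (noko). Of the 30 groups, 29 held 2 libraries and the siPKC group given AP20187 held 1, for which no SD can be given.

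Levels below are in TPM, as mean ± SD with n = 2 per group, and fold changes are differences of log2(TPM + 1), a scale that understates the change of genes with low values. Within groups, the correlation of log2 values between replicates across genes (which are not independent replicates) lay between 0.985 and 0.994. The labels do not state whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Sequencing depth is unknown, because TPM keeps no depth. Mouse genes were named as in the deposited table, and several of those followed throughout have these positions in mm10: Cxcl1 (ENSMUSG00000029380.11) on chromosome 5 at 90891241 to 90893115, Egr1 (ENSMUSG00000038418.7) on chromosome 18 at 34859823 to 34864984, Ccl2 on chromosome 11 at 82035571 to 82037453, Ier3 on chromosome 17 at 35821684 to 35822923 and Nfkbia on chromosome 12 at 55489410 to 55492647. A number alone in parentheses after a gene is its log2 fold change.

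A common set of inflammatory and immediate early genes was higher in both mouse lines after MLKL dimerization, GSDMD release or digitonin. MLKL cells in calcium-free medium, described below, are not among these comparisons. The chemokine gene Cxcl1, the transcription factor gene Egr1, the cytokine genes Lif and Il11, the transcription factor genes Fos, Fosb and Junb, the inducible cyclooxygenase gene Ptgs2, and Ier3, Ereg, Nfkbiz and Rgs16 were at least 2-fold higher in all 6 mouse comparisons of MLKL, GSDMD or digitonin in NIH3T3 and LLC cells. The smallest of the 6 log2 fold changes was 3.29 for Cxcl1, 2.30 for Egr1 and 2.08 for Lif. Past the threshold, 241 genes were higher in all 6, against 0.432 expected of independent lists among the 10003 genes tested in each. The number of genes that passed (limma, Benjamini-Hochberg adjusted p under 0.05) ran from 35 of 11504 in parental NIH3T3 cells given AP20187 to 10902 of 13566 in BxPC3 cells given digitonin. In 8 comparisons the median log2 fold change of all tested genes lay more than 0.1 below 0, from -0.14 to -0.37, so the numbers of lower genes there are given beside those found after centring each library on its median.

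**Figure D1:**
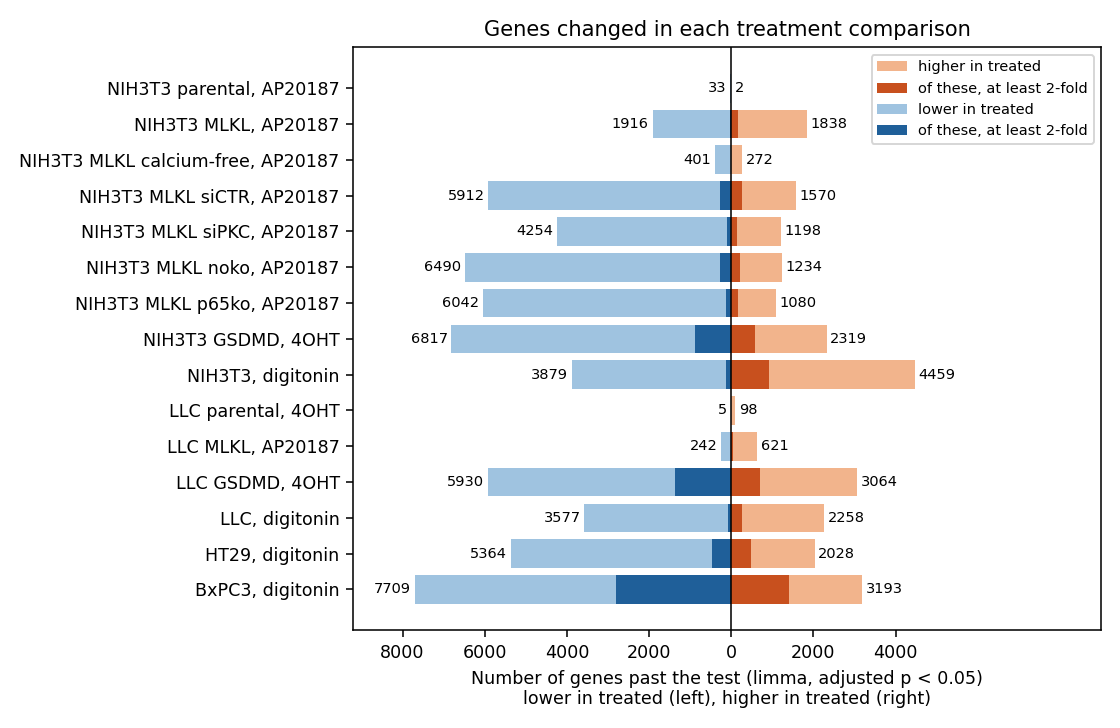
Number of genes past the threshold (limma, Benjamini-Hochberg adjusted p under 0.05) in each of the 15 treatment comparisons, with genes higher after treatment to the right and genes lower to the left, and the part changed at least 2-fold drawn darker. Parental cells given a ligand show 35 genes (NIH3T3) and 103 genes (LLC), and BxPC3 cells given digitonin show 10902.

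Of 19 gene lists fixed in advance, 18 were measured, and the 13 mitochondrially encoded genes were not analysed. Camera with a preset correlation called 140 shifts of a list over 12 permeabilization comparisons, and 105 held with an estimated one. Parental cells and calcium-free medium, where cholesterol genes fell, are not among these 12. Cytokine and chemokine genes, immediate early genes, NF-kB target genes, calcium, NFAT and CREB responsive genes and cholesterol genes stood above the other genes in all 12, and each held. ERK feedback genes did so in 12 (11 held), the unfolded protein and integrated stress response in 11 (all held) and p53 target genes in 12 (8 held). Heat shock genes were called in 11 (3 held). Where a list is reported below without a second count, the count adjusted over the list alone was the same.

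**Figure D2:**
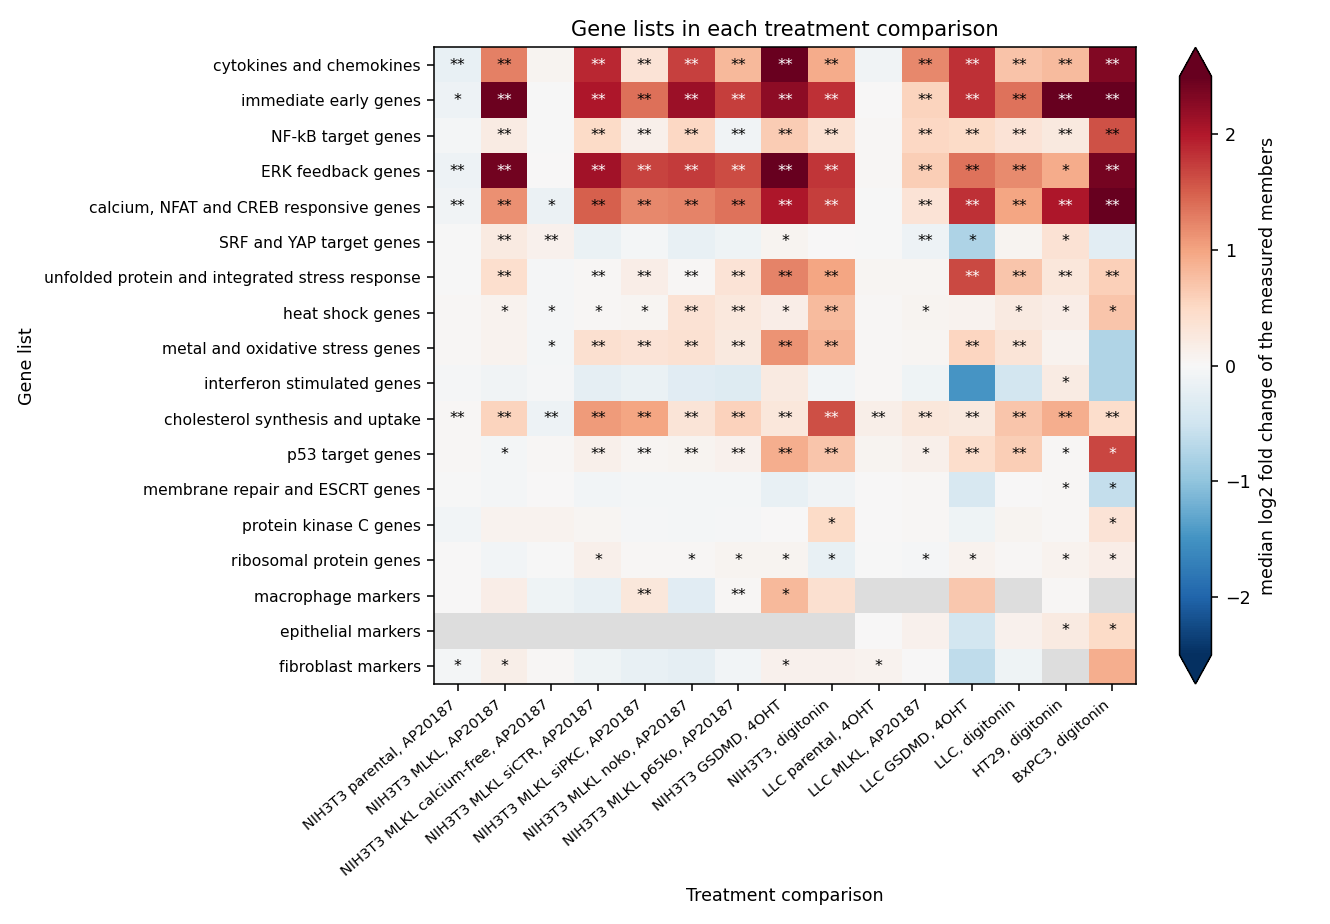
Median log2 fold change of the measured members of each gene list (vertical) in each treatment comparison (horizontal), on a colour scale from -2.5 to 2.5. A single star marks a camera call with the preset correlation (adjusted p under 0.05), a double star a call that also held with an estimated correlation, and grey a list with fewer than 3 measured members.

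Dimerization of MLKL in NIH3T3 cells raised immediate early and inflammatory genes within 1 h. Egr1 (from 4.26 ± 0.0962 to 867 ± 58.7 TPM, log2 fold change 7.37, SE 0.067) and Cxcl1 (from 7.63 ± 0.103 to 247 ± 22.2 TPM, log2 fold change 4.84, SE 0.10), the neutrophil chemokine, were among the largest rises (limma, Benjamini-Hochberg adjusted p = 9.35e-26 and 1.48e-19). 24 of 24 measured immediate early genes rose, with a median log2 fold change of 2.45, among them Fos (from 0.755 to 44.8 TPM, log2 fold change 4.71), Ier3 (from 31.1 to 837 TPM, log2 fold change 4.71) and Jun (from 42.2 to 789.9 TPM, log2 fold change 4.19). Of 14 measured cytokine and chemokine genes, 11 rose and 3 did not pass, including Lif (from 6.77 to 156 TPM, log2 fold change 4.34), an interleukin-6 family cytokine, Ccl2 (1.93), the monocyte chemokine, and Cxcl10 (2.32). 10 of 20 measured NF-kB target genes rose, 1 fell and 9 did not pass (adjusted over the list alone, 11 rose and 2 fell), with Nfkbia (2.39), Tnfaip3 (3.08) and Nfkbiz (3.49). Of 17 measured ERK feedback genes, 14 rose and 3 did not pass, such as the phosphatase Dusp6 (3.58) and Errfi1 (3.41). 13 of 16 measured calcium, NFAT and CREB responsive genes rose, 2 fell and 1 did not pass, such as Rcan1 (3.57) and Ptgs2 (4.06). Of 17 measured SRF and YAP target genes, 12 rose and 5 did not pass, led by Cyr61 (4.64) and Ctgf (2.82), matricellular proteins.

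Cholesterol genes rose less far: 15 of 18 measured cholesterol synthesis and uptake genes rose and 3 did not pass (adjusted over the list alone, 15 rose and 1 fell), with Insig1 (from 175 to 448 TPM, log2 fold change 1.35) and Hmgcs1 (1.39). 10 of 16 measured unfolded protein and integrated stress response genes rose and 6 did not pass (adjusted over the list alone, 11 rose), with Chac1 (from 10.7 to 106 TPM, log2 fold change 3.20) highest, followed by Ppp1r15a (2.18) and Ddit3 (1.19). Of 13 measured heat shock genes, 5 rose, 1 fell and 7 did not pass (adjusted over the list alone, 7 rose and 1 fell, camera adjusted p = 0.00391, adjusted p = 0.143 with an estimated correlation). 5 of 14 measured p53 target genes rose, 3 fell and 6 did not pass, and 5 rose and 4 fell after median centring and 5 rose and 5 fell after quantile normalization; the median of this list was -0.044, its mean 0.57 and its camera call upward (adjusted p = 0.0299, adjusted p = 0.0552 with an estimated correlation). Of 12 measured metal and oxidative stress genes, 5 rose, 2 fell and 5 did not pass (camera adjusted p = 0.263), with Hmox1 (1.36) up and Txnip (-0.94) down. 2 of 19 measured membrane repair and ESCRT genes fell and 17 did not pass (adjusted over the list alone, 1 fell, camera adjusted p = 0.263). The largest falls were in Cdc42ep2 (from 53.2 to 16.2 TPM, log2 fold change -1.67), Cbx2 (-1.73), Hoxa2 (-1.37) and Zfp87 (-1.35). In all, 1838 genes were higher and 1916 lower, 169 and 28 of them at least 2-fold. Leaving out untreated replicate 1 lowered the total from 3754 to 2500, and each other library left at most 3175.

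Parental NIH3T3 cells given the same dimerizer did not show these rises. Cxcl1 was 8.48 ± 0.317 TPM after AP20187 and 13.2 ± 0.0490 without (log2 fold change -0.58, SE 0.10), and Egr1 was 6.6 ± 0.292 and 6.24 ± 0.267 TPM (limma, Benjamini-Hochberg adjusted p = 0.951). Of 35 genes past the threshold, 33 were lower, by small amounts, among them Ccl2 (from 235 to 177 TPM, log2 fold change -0.41), Lif (-0.36), Ptgs2 (-0.32), Inhba (-0.48) and the nuclear RNA Neat1 (from 216 to 157 TPM), and 735 genes had an unadjusted p under 0.05. Of 11 measured cytokine and chemokine genes, 4 fell and 7 did not pass (adjusted over the list alone, 6 fell, camera adjusted p = 1.74e-07). 3 of 17 measured ERK feedback genes fell and 14 did not pass (adjusted over the list alone, 7 fell, camera adjusted p = 1.33e-11). Of 22 measured immediate early genes, 2 fell and 20 did not pass (adjusted over the list alone, 9 fell, camera adjusted p = 1.34e-07, adjusted p = 0.0525 with an estimated correlation). Leaving out any one of the 4 libraries gave 9 to 18 genes. Cxcl1 and Lif then failed to pass whichever library was left out (adjusted p = 0.0598 to 0.117 and 0.144 to 0.346), and Ptgs2 without untreated replicate 1 (0.0817) or treated replicate 2 (0.0598). On the libraries of the comparison alone none of Cxcl1, Ccl2, Lif, Ptgs2 and Inhba passed (adjusted p = 0.165, 0.148, 0.468, 0.379 and 0.313), and with a replicate block Cxcl1 and Lif did not (0.0931 and 0.116), nor Lif after median centring (0.0586) or without small RNA and ribosomal RNA (0.0750).

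Tested directly, the AP20187 response differed between MLKL and parental NIH3T3 cells in 2446 genes, 1479 with a larger and 967 with a smaller log2 fold change in MLKL cells, or 1306 and 1399 after median centring and 1311 and 1593 after quantile normalization. The differences in log2 fold change included Egr1 (7.29, SE 0.095), Cxcl1 (5.42, SE 0.14), Ier3 (4.88, SE 0.085), Cyr61 (4.78, SE 0.062) and Lif (4.70, SE 0.10), and reached 2.56 for Nfkbia and 2.34 for Ccl2 (limma, Benjamini-Hochberg adjusted p = 5.56e-20 and 2.59e-16). Cbx2 (-1.72), Cdc42ep2 (-1.64) and Id3 (-1.38) differed in the other direction.

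**Figure D3:**
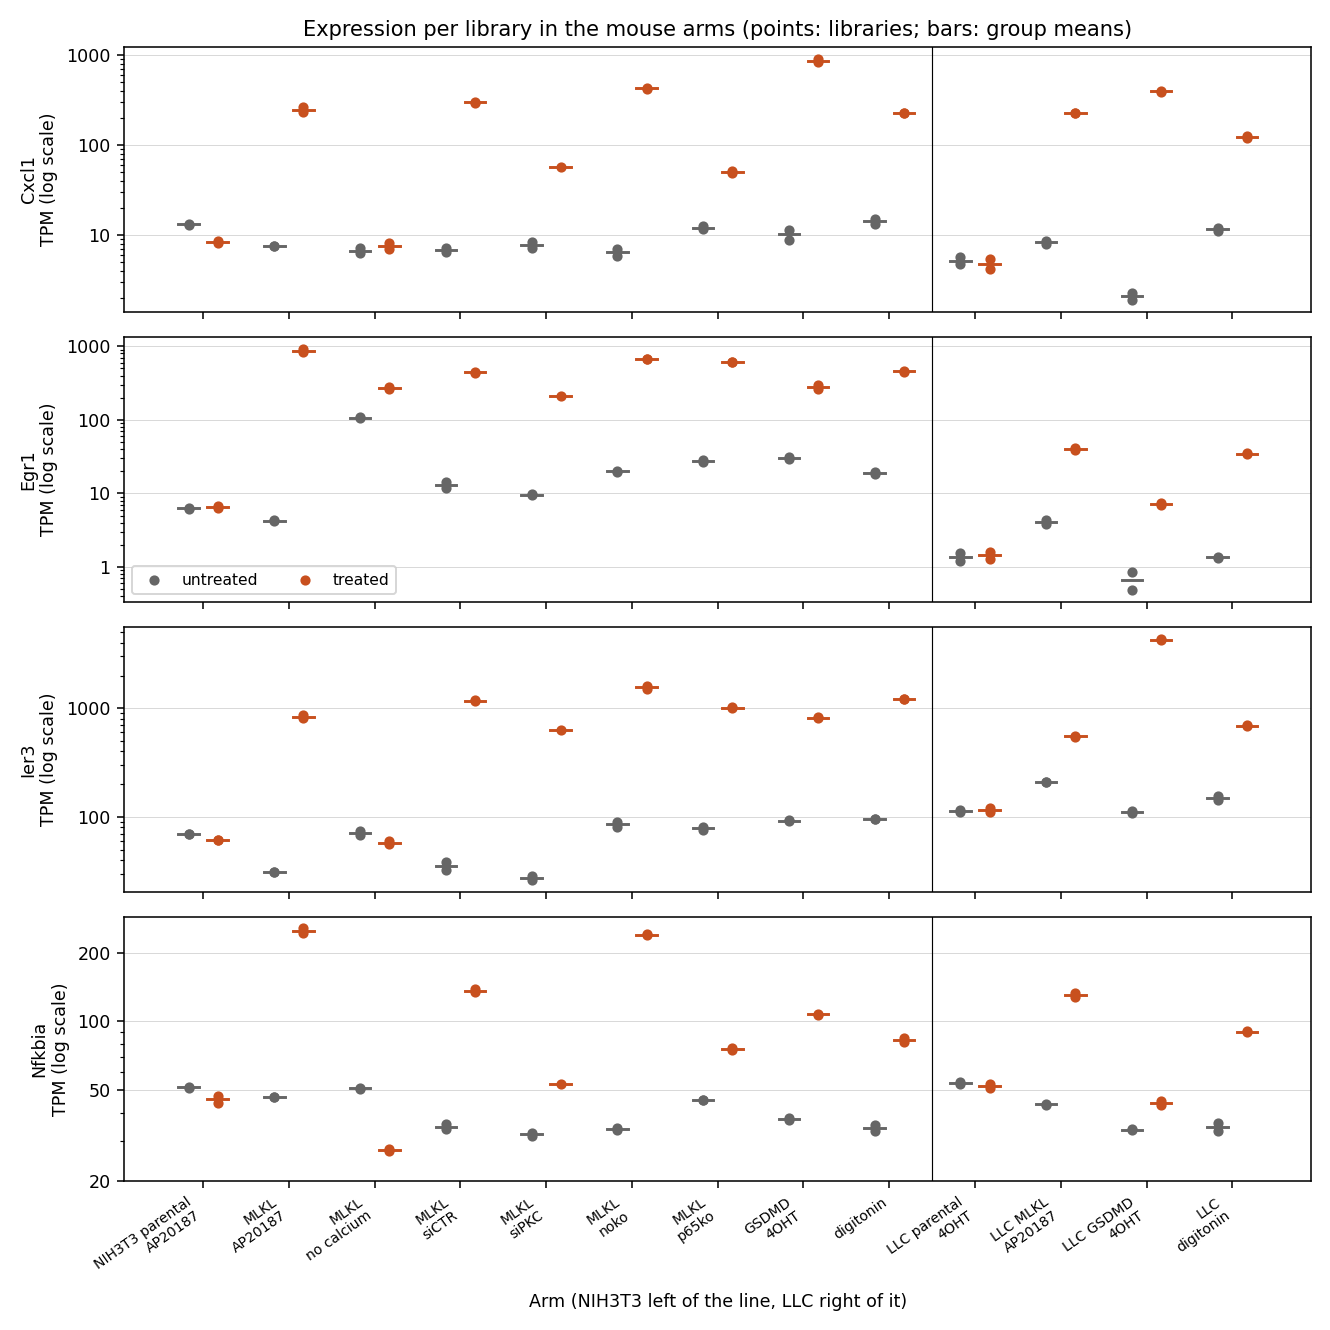
TPM of Cxcl1, Egr1, Ier3 and Nfkbia in every mouse library (log axis), with each point 1 library (grey untreated, orange treated), short bars for group means, and NIH3T3 arms left and LLC arms right of the vertical line. Cxcl1 lies at 7.63 TPM in untreated and 247 TPM in AP20187-treated NIH3T3 MLKL cells, and at 2.12 and 396 TPM in LLC GSDMD cells without and with 4OHT.

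The question of extracellular calcium was addressed with the same MLKL cells in calcium-free medium, where most of the response was missing. Cxcl1 was 7.67 ± 0.764 TPM with AP20187 and 6.74 ± 0.612 without (limma, Benjamini-Hochberg adjusted p = 0.397), Ccl2 was 223 ± 3.64 and 212 ± 2.22 (adjusted p = 0.441), and Tnfaip3 1.27 and 1.02. Egr1 (from 107 ± 2.58 to 271 ± 7.55 TPM, log2 fold change 1.34, SE 0.067) still rose, as did Cyr61 (from 27.3 to 49.6 TPM, log2 fold change 0.84), Ctgf (from 130.3 to 217 TPM, log2 fold change 0.73), Fos (0.62) and Lif (0.28). 6 of 17 measured SRF and YAP target genes rose and 11 did not pass (adjusted over the list alone, 8 rose, camera adjusted p = 4.31e-10). Others fell: Nfkbia (from 51.0 ± 0.499 to 27.5 ± 0.329 TPM, log2 fold change -0.87, SE 0.034), Ier3 (-0.30), Insig1 (-0.35), Hmgcs1 (-0.30), Txnip (-0.48) and Klf11 (-0.81). Of 18 measured cholesterol synthesis and uptake genes, 7 fell and 11 did not pass (adjusted over the list alone, 11 fell, camera adjusted p = 5.85e-10), the reverse of the direction in complete medium. 5 of 23 measured immediate early genes rose, 7 fell and 11 did not pass (adjusted over the list alone, 8 rose and 8 fell, camera adjusted p = 0.523). Of 13 measured cytokine and chemokine genes, 2 rose and 11 did not pass (camera adjusted p = 0.158). 1 of 19 measured NF-kB target genes rose, 1 fell and 17 did not pass (adjusted over the list alone, 2 rose and 2 fell, camera adjusted p = 0.557). Of 15 measured calcium, NFAT and CREB responsive genes, 1 rose, 3 fell and 11 did not pass (adjusted over the list alone, 1 rose and 6 fell, camera adjusted p = 0.00599, adjusted p = 0.0583 with an estimated correlation). 2 of 12 measured metal and oxidative stress genes fell and 10 did not pass (adjusted over the list alone, 3 fell, camera adjusted p = 0.00684, adjusted p = 0.0583 with an estimated correlation). In total 272 genes were higher and 401 lower (246 and 593 after median centring), 4 and 2 at least 2-fold, and leaving out any one of the 4 libraries gave 278 to 388 genes. Lif did not pass without untreated replicate 2 (adjusted p = 0.290), treated replicate 1 (0.119) or treated replicate 2 (0.110), nor Ier3 without untreated replicate 2 (0.0711) or treated replicate 1 (0.0559). On the libraries of the comparison alone Fos, Lif, Hmgcs1 and Ier3 did not pass (adjusted p = 0.104, 0.216, 0.0513 and 0.106).

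The log2 fold change of the genes that led the response was lower in calcium-free than in complete medium. The difference in log2 fold change was -6.02 (SE 0.095) for Egr1, -5.01 for Ier3, -4.85 for the mRNA-decay factor Zfp36, -4.68 for Cxcl1, -4.09 for Fos, -4.06 for Lif, -3.26 for Nfkbia and -1.86 for Ccl2, each past the threshold (limma, Benjamini-Hochberg adjusted p = 3.2e-21 for Egr1 and 1.69e-14 for Ccl2). Untreated levels also differed by value: Egr1 was 107 ± 2.58 TPM in calcium-free and 4.26 ± 0.0962 TPM in complete medium, and with AP20187 271 ± 7.55 and 867 ± 58.7 TPM. By the test of the difference, 24 of 24 immediate early genes had a lower log2 fold change (camera adjusted p = 2.84e-59), as had 11 of 15 cytokine and chemokine genes, 9 of 20 NF-kB target genes, 13 of 17 ERK feedback genes and 13 of 18 cholesterol genes. Cdc42ep2 (1.67) and Cbx2 (1.36), which fell in complete medium, and Id3 (1.35) differed upward. The difference passed for 2593 genes, 1280 upward and 1313 downward.

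NIH3T3 cells with the GSDMD construct held 1182 ± 67.7 TPM of Gsdmd without and 728 ± 26.3 TPM with 4OHT, against 5.79 ± 0.493 TPM in untreated parental cells. Release of the GSDMD fragment for 2.5 h raised cytokine and chemokine, immediate early and stress response genes. Cxcl1 (from 10.3 ± 1.88 to 865 ± 41.8 TPM, log2 fold change 6.27, SE 0.10) rose most (limma, Benjamini-Hochberg adjusted p = 9.84e-22). With it rose Lif (from 11.8 to 288 TPM, log2 fold change 4.50), Ccl2 (from 218 to 1354 TPM, log2 fold change 2.63), Vegfa (from 97.6 to 808 TPM, log2 fold change 3.04), Cxcl10 (4.62) and Il6 (2.99). Of 15 measured cytokine and chemokine genes, 14 rose and 1 did not pass, with a median log2 fold change of 2.47. 24 of 25 measured immediate early genes rose and 1 did not pass, such as Fosb (5.14), Egr1 (3.16), Ier3 (3.14) and Fos (2.76). Of 16 measured calcium, NFAT and CREB responsive genes, 15 rose and 1 did not pass, such as Ptgs2 (2.98). 15 of 17 measured ERK feedback genes rose and 2 fell, such as Dusp4 (4.36) and Hbegf (3.49). Of 21 measured NF-kB target genes, 14 rose, 3 fell and 4 did not pass, and Nfkbia (1.5) rose less than in MLKL cells by value. 9 of 12 measured metal and oxidative stress genes rose and 3 fell, with Hmox1 (4.28), the heme-degrading enzyme, and Srxn1 (2.49) as examples. 12 of 16 measured unfolded protein and integrated stress response genes rose, 3 fell and 1 did not pass, led by Chac1 (4.80), Ppp1r15a (2.97) and Herpud1 (2.11). 8 of 14 measured p53 target genes rose and 6 fell, among them Plk3 (4.05), Cdkn1a (2.12) and Mdm2 (2.31). Of 18 measured cholesterol synthesis and uptake genes, 10 rose, 7 fell and 1 did not pass (median 0.28), among them Insig1 (1.24).

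Among the genes that fell were Hoxa3 (from 38.1 to 4.8 TPM, log2 fold change -2.75), Ifit2 (-1.68), Birc2 (-1.51) and the cytoskeletal actin Actb (from 3096 to 1402 TPM, log2 fold change -1.14). 3 of 19 measured membrane repair and ESCRT genes rose, 14 fell and 2 did not pass (camera adjusted p = 0.493), including Chmp6 (-1.05); here 7 rose and 5 fell after median centring and 3 rose and 11 fell after quantile normalization. For SRF and YAP target genes the split was 8 up and 8 down of 17 (camera adjusted p = 0.0433, adjusted p = 0.246 with an estimated correlation), and 11 rose and 5 fell after median centring and 9 rose and 7 fell after quantile normalization. Of 13 measured heat shock genes, 7 rose, 5 fell and 1 did not pass (adjusted over the list alone, 7 rose and 6 fell, camera adjusted p = 0.0192, adjusted p = 0.234 with an estimated correlation), and the median of that list, 0.16, turned to -0.1 after quantile normalization. 6 of 20 measured ribosomal protein genes rose, 2 fell and 12 did not pass (adjusted over the list alone, 2 rose and 1 fell, camera adjusted p = 0.00975, adjusted p = 0.427 with an estimated correlation), and 20 rose after median centring and 2 rose and 9 fell after quantile normalization. Of 5 measured interferon stimulated genes, 1 rose, 2 fell and 2 did not pass (camera adjusted p = 0.939), and 3 rose and 2 fell after median centring and 3 rose and 2 fell after quantile normalization. Of 11632 genes, 2319 were higher and 6817 lower with a median log2 fold change of -0.29. After median centring 4142 genes were called higher and 4177 lower, 877 and 292 of them at least 2-fold. No parental NIH3T3 cells given 4OHT were part of the design.

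Digitonin, which permeabilizes without either protein, raised much the same kinds of genes in NIH3T3 cells after 3 h. Egr1 (from 18.8 ± 0.732 to 454 ± 13.0 TPM, log2 fold change 4.53, SE 0.067) and Cxcl1 (from 14.3 ± 1.37 to 228 ± 0.955 TPM, log2 fold change 3.91, SE 0.10) rose (limma, Benjamini-Hochberg adjusted p = 2.51e-18 for Cxcl1). Other large rises were in Fosb (from 5.94 to 133 TPM, log2 fold change 4.27), Csrnp1 (from 5.09 to 97.3 TPM, log2 fold change 4.01), Inhba (from 12.7 to 209 TPM, log2 fold change 3.93), a TGF-beta family subunit, and Ier3 (from 95.8 to 1209 TPM, log2 fold change 3.64). 24 of 24 measured immediate early genes rose. Of 18 measured ERK feedback genes, 17 rose and 1 fell, with Ereg (2.83) up. 15 of 16 measured calcium, NFAT and CREB responsive genes rose and 1 did not pass, with Ptgs2 (3.17) as an example. With digitonin, 17 of 18 measured cholesterol synthesis and uptake genes rose and 1 fell, with a median log2 fold change of 1.6, and Hmgcs1 (3.12) and Insig1 (2.80) showed the size of it. Of 16 measured cytokine and chemokine genes, 12 rose, 3 fell and 1 did not pass, with Lif (2.61) and Il11 (2.69) up and Ccl2 (0.25) little above its untreated level (adjusted p = 0.0760 after median centring). 12 of 20 measured NF-kB target genes rose, 4 fell and 4 did not pass, with Nfkbia (1.25) and Tnfaip3 (1.42). In these cells 12 of 13 measured heat shock genes rose and 1 fell, Dnajb1 (1.78) among them. 14 of 16 measured unfolded protein and integrated stress response genes rose and 2 fell. 9 of 12 measured metal and oxidative stress genes rose, 2 fell and 1 did not pass, with Hmox1 (2.46). Of 14 measured p53 target genes, 10 rose, 2 fell and 2 did not pass. 4 of 19 measured membrane repair and ESCRT genes rose, 9 fell and 6 did not pass (camera adjusted p = 0.233), including Chmp6 (-1.07). Of 20 measured ribosomal protein genes, 16 fell and 4 did not pass (camera adjusted p = 0.00081, adjusted p = 0.361 with an estimated correlation), while the median of that list was 0.0716 once the transcript length trend was removed. The SRF and YAP targets split 8 up and 7 down of 17, with Ctgf (-1.37) down, and 8 rose and 9 fell after median centring and 8 rose and 8 fell after quantile normalization.

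The untreated libraries of this arm stood apart from the other untreated NIH3T3 groups in 230 of 10269 genes, by more than 1 log2 unit outside their range, against at most 99 for any other group, and their difference fell with transcript length (Spearman rho = -0.597 across genes, which are not independent replicates). Digitonin was associated with 4459 higher and 3879 lower genes, 3611 and 5148 after median centring and 3738 and 4868 after quantile normalization. Against the untreated parental libraries instead, an alternative chosen after the data were seen, 2565 genes were higher and 6384 lower, and 275 of the 921 genes that had been at least 2-fold higher were so again. The log2 fold change was then 4.02 for Cxcl1, 5.98 for Egr1, 4.10 for Ier3 and 4.02 for Lif, but 1.03 for Hmgcs1 and 1.21 for Insig1, in place of 3.12 and 2.80, which were 3.08 and 2.88 with the transcript length trend removed.

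In LLC carcinoma cells, Gsdmd was 376 ± 0.755 TPM in untreated GSDMD cells against 22.6 ± 0.000424 TPM in untreated parental cells. With 4OHT these cells showed the largest log2 fold change of Cxcl1 among the mouse comparisons by value. Cxcl1 (from 2.12 ± 0.260 to 396 ± 7.68 TPM, log2 fold change 6.99, SE 0.10) and Ier3 (from 111 ± 2.58 to 4278 ± 56.0 TPM, log2 fold change 5.25, SE 0.045) were among the largest rises (limma, Benjamini-Hochberg adjusted p = 2.5e-13 for Cxcl1). So were Ptgs2 (from 51.2 to 2055 TPM, log2 fold change 5.30), Chac1 (from 4.4 to 431 TPM, log2 fold change 6.33), a glutathione-degrading enzyme of the stress response, the transcription factor Atf3 (from 0.791 to 105 TPM, log2 fold change 5.89) and Il11 (from 11.3 to 361 TPM, log2 fold change 4.88). 10 of 13 measured cytokine and chemokine genes rose and 3 fell, among them Cxcl2 (4.69), Lif (3.35) and Ccl2 (1.83). Of 23 measured immediate early genes, 21 rose and 2 fell, among them Egr1 (2.30). 13 of 16 measured unfolded protein and integrated stress response genes rose and 3 fell, with a median of 1.66, the examples being Ppp1r15a (3.65), Herpud1 (3.19) and Nupr1 (4.41); the hormone gene Fgf21 was listed at 0 without and at 19.8 TPM with 4OHT. Of 19 measured ERK feedback genes, 16 rose and 3 fell, with Dusp1 (4.31) and Areg (2.91). 13 of 14 measured calcium, NFAT and CREB responsive genes rose and 1 fell. Of 12 measured metal and oxidative stress genes, 9 rose, 2 fell and 1 did not pass, with Slc7a11 (3.24) and Hmox1 (2.12). 12 of 19 measured NF-kB target genes rose, 6 fell and 1 did not pass, with Nfkbiz (2.82) up, Nfkbia (0.37) barely up and the adhesion molecule Vcam1 (-2.16) down. Of 15 measured p53 target genes, 10 rose, 3 fell and 2 did not pass. 11 of 18 measured cholesterol synthesis and uptake genes rose, 5 fell and 2 did not pass, with Insig1 (2.25). Of 14 measured heat shock genes, 6 rose, 5 fell and 3 did not pass, with Hspa1b (2.77). 1 of 14 measured SRF and YAP target genes rose, 10 fell and 3 did not pass (camera adjusted p = 0.0470, adjusted p = 0.180 with an estimated correlation), with Actb (-1.53), Actg1 (-1.74) and, outside the list, Cnn2 (-2.95) as examples. Of 18 measured membrane repair and ESCRT genes, 3 rose, 12 fell and 3 did not pass (camera adjusted p = 0.186), including Chmp6 (-1.69). 3 of 3 measured interferon stimulated genes fell (camera adjusted p = 0.132), among them Ifit2 (-1.48). Of 20 measured ribosomal protein genes, 12 rose, 2 fell and 6 did not pass (camera adjusted p = 0.00587, adjusted p = 0.080 with an estimated correlation). Of 10976 genes 3064 were higher and 5930 lower with a median of -0.25 (3944 and 4895 after median centring).

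Parental LLC cells given 4OHT did not show the rise of Cxcl1, which was 4.83 ± 0.860 TPM with and 5.24 ± 0.656 TPM without (limma, Benjamini-Hochberg adjusted p = 0.781), and Ccl2 (from 136 to 116 TPM, log2 fold change -0.23) was slightly lower. Of 98 higher genes, 4 were at least 2-fold higher, among them small RNA genes. Smaller rises included Syne2 (0.62), Hspg2 (0.58), Dst (0.58), Lrp1 (0.53) and Dync1h1 (0.50), which encode very large proteins, and the log2 fold changes of this comparison rose with transcript length (rho = 0.334 across genes). 1 of 18 measured cholesterol synthesis and uptake genes rose and 17 did not pass (adjusted over the list alone, 9 rose, camera adjusted p = 1.42e-07), with none past the threshold after median centring or quantile normalization. Of 5 measured fibroblast marker genes, 1 rose and 4 did not pass (adjusted over the list alone, 3 rose, camera adjusted p = 0.00156, adjusted p = 0.0926 with an estimated correlation). Leaving out any one of the 4 libraries gave 12 to 33 genes in place of 103. Ccl2 did not pass without untreated replicate 1 (adjusted p = 0.0740), untreated replicate 2 (0.156) or treated replicate 2 (0.263), nor Syne2 without treated replicate 2 (0.0570), and neither did on the libraries of the comparison alone (0.214 and 0.1), nor Ccl2 with a replicate block (0.0779).

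The 4OHT response differed between GSDMD and parental LLC cells in 8268 genes, 2584 upward and 5684 downward (3631 and 4305 after median centring). The differences in log2 fold change were 7.09 (SE 0.14) for Cxcl1, 6.23 for Chac1, 5.83 for Atf3, 5.32 for Ptgs2, 5.23 for Ier3, 2.06 for Ccl2 and 2.25 for Egr1, and -1.51 for Actb, -2.15 for Vcam1 and -2.94 for Cnn2 (limma, Benjamini-Hochberg adjusted p = 1.33e-11 for Cxcl1 and 3.03e-13 for Cnn2).

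MLKL dimerization for 1 h passed for 863 genes in LLC cells. Cxcl1 (from 8.34 ± 0.594 to 229 ± 0.60 TPM, log2 fold change 4.62, SE 0.10) and Egr1 (from 4.06 ± 0.376 to 40.4 ± 2.04 TPM, log2 fold change 3.03, SE 0.11) were among the largest rises (limma, Benjamini-Hochberg adjusted p = 1.93e-10 for Cxcl1). With them rose Cxcl2 (from 0.0317 to 7.93 TPM, log2 fold change 3.11), Lif (from 4.73 to 23.2 TPM, log2 fold change 2.08), Cxcl5 (from 2.57 to 13.0 TPM, log2 fold change 1.97), Ccl2 (from 176 to 684 TPM, log2 fold change 1.95) and Ptgs2 (1.67). 12 of 14 measured cytokine and chemokine genes rose, 1 fell and 1 did not pass. Of 23 measured immediate early genes, 19 rose and 4 did not pass (adjusted over the list alone, 21 rose), with Ier3 (1.40), Fosb (1.90) and Fos (1.54). 13 of 20 measured NF-kB target genes rose and 7 did not pass (adjusted over the list alone, 16 rose), with Nfkbia (1.57), Tnfaip3 (1.69) and Nfkbiz (1.58). Of 18 measured ERK feedback genes, 14 rose and 4 did not pass, Areg (1.13) among them. 7 of 14 measured calcium, NFAT and CREB responsive genes rose and 7 did not pass (adjusted over the list alone, 9 rose). Of 18 measured cholesterol synthesis and uptake genes, 11 rose and 7 did not pass (adjusted over the list alone, 13 rose and 1 fell). 7 of 16 measured SRF and YAP target genes fell and 9 did not pass (adjusted over the list alone, 9 fell, camera adjusted p = 5.49e-06), including Ankrd1 (-0.70), Amotl2 (-0.52) and Ajuba (-0.45). 4 of 16 measured unfolded protein and integrated stress response genes rose, 3 fell and 9 did not pass (adjusted over the list alone, 6 rose and 5 fell, camera adjusted p = 0.637), with Chac1 (-0.67) among those that fell. 2 of 13 measured heat shock genes rose and 11 did not pass (adjusted over the list alone, 3 rose, camera adjusted p = 0.0156, adjusted p = 0.107 with an estimated correlation). Of 14 measured p53 target genes, 6 rose, 1 fell and 7 did not pass (adjusted over the list alone, 6 rose and 3 fell, camera adjusted p = 0.0206, adjusted p = 0.0605 with an estimated correlation). Of 20 measured ribosomal protein genes, 20 did not pass (camera adjusted p = 0.0156, adjusted p = 0.108 with an estimated correlation, downward). Atoh8 (-0.96) and Cdc42ep2 (-0.77) fell. In total 621 genes were higher and 242 lower, 35 and 5 at least 2-fold, and leaving out any one of the 4 libraries gave 379 to 426 genes. Chac1 did not pass without untreated replicate 1 (adjusted p = 0.0592), untreated replicate 2 (0.0598) or the second treated library (0.0917). Of the higher genes, 393 were also higher in NIH3T3 MLKL cells, against 93.3 expected of independent lists.

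Digitonin for 3 h raised immediate early, chemokine and cholesterol genes in LLC cells. Fosb (from 0.477 ± 0.146 to 45.2 ± 1.34 TPM, log2 fold change 4.97, SE 0.11), Egr1 (from 1.35 ± 0.0155 to 34.8 ± 0.646 TPM, log2 fold change 3.93, SE 0.11), Atf3 (from 2.91 to 53.5 TPM, log2 fold change 3.80), Csrnp1 (from 2.69 to 42.1 TPM, log2 fold change 3.55), Cxcl1 (from 11.7 to 123 TPM, log2 fold change 3.29) and Klf2 (3.27) led (limma, Benjamini-Hochberg adjusted p = 3.42e-10 for Egr1). Of 23 measured immediate early genes, 23 rose. 8 of 12 measured cytokine and chemokine genes rose, 3 fell and 1 did not pass, among them Lif (from 2.18 to 21.0 TPM, log2 fold change 2.80), Il11 (2.42) and Cxcl2 (2.43) up and Ccl2 (-0.16) down. Of 18 measured NF-kB target genes, 12 rose, 3 fell and 3 did not pass, with Nfkbiz (1.93) and Nfkbia (1.36). 16 of 18 measured cholesterol synthesis and uptake genes rose and 2 did not pass, with Insig1 (1.61). 13 of 16 measured unfolded protein and integrated stress response genes rose and 3 did not pass (adjusted over the list alone, 14 rose), with Chac1 (3.02). 10 of 12 measured metal and oxidative stress genes rose and 2 fell. Of 19 measured ERK feedback genes, 15 rose, 2 fell and 2 did not pass, with Ier3 (2.20). 11 of 14 measured calcium, NFAT and CREB responsive genes rose, 1 fell and 2 did not pass, with Ptgs2 (2.53). Of 14 measured p53 target genes, 9 rose, 1 fell and 4 did not pass, with Cdkn1a (1.74). 7 of 13 measured heat shock genes rose, 2 fell and 4 did not pass (camera adjusted p = 0.00234, adjusted p = 0.0534 with an estimated correlation), with Hspa1b (1.95). Of 18 measured membrane repair and ESCRT genes, 5 rose, 5 fell and 8 did not pass (camera adjusted p = 0.690). Atoh8 (-2.66) and Hoxa6 (-1.89) were among the largest falls, and Actb (-0.42) and Chmp6 (-0.68) also fell. Ccl2 did not pass without treated replicate 2 (adjusted p = 0.0540). 2258 genes were higher and 3577 lower. The cells of this arm are labelled as carrying no construct, yet Gsdmd was 335 ± 2.57 TPM in untreated and 331 ± 6.82 TPM in digitonin-treated libraries, near the level of GSDMD cells.

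In the siRNA experiment, Prkca was 31.8 ± 1.24 TPM without and 32.3 ± 1.65 TPM with AP20187 after siCTR, and 7.75 ± 0.419 TPM without and 6.72 TPM with AP20187 (n = 1) after siPKC, a log2 fold change of -1.91 between the untreated groups (limma, Benjamini-Hochberg adjusted p = 4e-19). Other protein kinase C genes moved less: Prkcd (0.59) and Prkce (0.25) were higher and Prkci (-0.40) lower, and Prkd1, Prkd2 and Prkd3 did not pass, nor did Prkce without untreated replicate 2 of siCTR (adjusted p = 0.0556) or of siPKC (0.0803), or on these 4 libraries alone (0.114). Which gene the siRNA targets is not stated in the labels. Among genes higher in untreated siPKC cells were Acta2 (from 37.8 to 425 TPM, log2 fold change 3.46), Tagln (from 36.8 to 259 TPM, log2 fold change 2.78), Myl9 (from 14.1 to 111 TPM, log2 fold change 2.90), Col1a1 (from 191 to 854 TPM, log2 fold change 2.15) and Ctgf (1.18). Higher too were 16 of 17 SRF and YAP target genes (camera adjusted p = 1.06e-15) and 8 of 9 fibroblast marker genes, with 1 lower (camera adjusted p = 6.58e-06, adjusted p = 0.0671 with an estimated correlation). Ccl2 (-0.82), Il33 (-1.03) and Itgb7 (-1.74) were lower, 2748 genes in all were higher and 2511 lower.

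With siCTR, AP20187 raised Cxcl1 (from 6.89 to 299.8 TPM, log2 fold change 5.25), Ier3 (from 35.5 to 1172 TPM, log2 fold change 5.01), Egr1 (from 13.1 to 442 TPM, log2 fold change 4.98), Lif (from 6.97 to 232 TPM, log2 fold change 4.88), Clcf1 (3.36), a cytokine of the same family as Lif, Ptgs2 (3.02), Ccl2 (1.89) and Nfkbia (1.94) (limma, Benjamini-Hochberg adjusted p = 2.45e-20 for Cxcl1). Untreated siCTR replicate 2 held 6.78% small RNA and ribosomal RNA, against 0.879% in replicate 1 and at most 2.35% in any other mouse library. Without it, 6866 genes passed for siCTR in place of 7482, 939 in place of 985 for the siPKC difference and 4453 in place of 5259 between the untreated groups. With those RNAs removed from all libraries instead the counts were 7947, 1272 and 5334. 24 of 24 measured immediate early genes rose. Of 17 measured cytokine and chemokine genes, 13 rose, 2 fell and 2 did not pass (adjusted over the list alone, 14 rose and 2 fell). 12 of 20 measured NF-kB target genes rose, 2 fell and 6 did not pass (adjusted over the list alone, 13 rose and 2 fell). Of 18 measured cholesterol synthesis and uptake genes, 16 rose, 1 fell and 1 did not pass, with Insig1 (2.40) and Hmgcs1 (2.38). 1 of 17 measured SRF and YAP target genes rose, 9 fell and 7 did not pass (camera adjusted p = 0.255), with Ctgf (-2.42), Amotl2 (-2.05) and Ajuba (-1.96) down, and 8 rose and 6 fell after median centring and 2 rose and 9 fell after quantile normalization. Of 20 measured ribosomal protein genes, 13 rose and 7 did not pass (camera adjusted p = 1.2e-06, adjusted p = 0.181 with an estimated correlation). 5 of 13 measured heat shock genes rose, 2 fell and 6 did not pass (camera adjusted p = 0.00175, adjusted p = 0.112 with an estimated correlation), and Ifit2 (-1.16) and Txnip (-1.47) fell. 1570 genes were higher and 5912 lower with a median of -0.19 (3514 and 2679 after median centring).

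With siPKC the single treated library held 57.2 TPM of Cxcl1 against 7.79 ± 0.849 TPM untreated (log2 fold change 2.73, SE 0.12), 69.4 against 7.77 ± 0.384 for Lif, 191 against 111 ± 0.822 for Ccl2 and 53.2 against 32.2 ± 0.60 for Nfkbia (limma, Benjamini-Hochberg adjusted p = 2.25e-11, with the lone library assumed to vary like the other groups). Ier3 (from 27.4 to 632 TPM, log2 fold change 4.48), Egr1 (from 9.63 to 211 TPM, log2 fold change 4.31) and Ptgs2 (from 221 to 1545 TPM, log2 fold change 2.80) still rose, and Tnfaip3 was 2.12 and 2.44 TPM (adjusted p = 0.391). With 1 treated library, genes under 1 TPM untreated were not tested. The 23 immediate early, 13 cytokine and chemokine and 17 NF-kB target genes left are fewer than with siCTR, so rises are not counted. Irf1 (-1.33) was lower. 16 of 18 measured cholesterol synthesis and uptake genes rose, 1 fell and 1 did not pass (adjusted over the list alone, 17 rose and 1 fell). 1198 genes were higher and 4254 lower with a median of -0.14 (2461 and 1943 after median centring).

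The difference in log2 fold change between the siPKC and siCTR responses was -2.52 (SE 0.16) for Cxcl1, -1.95 for Il6, -1.87 for Lif, -1.59 for Tnfaip3, -1.57 for Cxcl10, -1.23 for Nfkbia and -1.11 for Ccl2, and -0.67 for Egr1 and -0.53 for Ier3 (limma, Benjamini-Hochberg adjusted p = 1.4e-09 for Cxcl1 and 0.00132 for Ier3). Lower log2 fold changes with siPKC were found for 10 of 17 cytokine and chemokine genes (13 adjusted over the list alone; camera, adjusted p = 2.72e-17), 12 of 20 NF-kB target genes (14 adjusted over the list alone; adjusted p = 4.79e-16) and 15 of 24 immediate early genes (18 adjusted over the list alone; adjusted p = 1.67e-18). Upward differences were found for 5 of 17 SRF and YAP target genes (8 adjusted over the list alone; adjusted p = 2e-05), and that of Ctgf, 1.96, was a smaller fall, from -2.42 with siCTR to -0.46 with siPKC. The siPKC group given AP20187 held 1 library, so the SE, p-values and counts of this difference carry no spread of that group, and fitted on the libraries of the comparison alone 54 genes passed. Cxcl10, Egr1 and Ier3 were not among them (adjusted p = 0.158, 0.151 and 0.169), and Cxcl10 did not pass with a pseudocount of 0.1 either (adjusted p = 0.239). The difference passed for 985 genes, 592 upward and 393 downward (313 and 760 after median centring, 390 and 398 after quantile normalization), for 537 without siPKC untreated replicate 1 and for 588 without siCTR treated replicate 2.

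In the knockout experiment Rela, the gene of p65, was 49.4 ± 0.371 TPM in untreated and 93.2 ± 2.22 TPM in AP20187-treated noko cells, and 13.8 ± 0.343 and 19.4 ± 0.670 TPM in p65ko cells (log2 fold change -1.76 between the untreated groups; limma, Benjamini-Hochberg adjusted p = 1.68e-15), so transcript of the targeted gene remained. Untreated p65ko cells differed from noko cells in other ways: Rgcc (from 30.0 to 0.050 TPM), Btg3 (-4.20), Cbr1 (-3.71), Tspan6 (-3.56), Mt2 (from 79.0 to 6.7 TPM, log2 fold change -3.39) and Scara3 (-3.36) were lower. Cd209c (from 23.4 to 269 TPM, log2 fold change 3.46) and Ly6c1 (from 2.59 to 29.0 TPM, log2 fold change 3.06) were higher, and Cxcl1 (from 6.5 to 12.1 TPM, log2 fold change 0.81), Ccl2 (0.42) and Nfkbia (0.41) slightly higher. All 18 of 18 cholesterol synthesis and uptake genes were lower (camera adjusted p = 9.09e-25), such as Lss (-1.21), Fdft1 (-1.14) and Insig1 (-0.76). 3822 genes were higher and 1822 lower (2413 and 2787 after median centring).

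In noko cells AP20187 raised Cxcl1 (from 6.5 to 427 TPM, log2 fold change 5.84), Egr1 (from 19.9 to 671 TPM, log2 fold change 5.01), Ier3 (from 85.7 to 1559 TPM, log2 fold change 4.17), Lif (from 19.4 to 269.8 TPM, log2 fold change 3.73), Nfkbia (2.78), Ccl2 (1.66) and Tnfaip3 (2.68) (limma, Benjamini-Hochberg adjusted p = 6.66e-21 for Cxcl1). Of 24 measured immediate early genes, 24 rose. 13 of 16 measured cytokine and chemokine genes rose, 2 fell and 1 did not pass. Of 20 measured NF-kB target genes, 12 rose, 1 fell and 7 did not pass. 14 of 18 measured ERK feedback genes rose and 4 fell. Of 17 measured SRF and YAP target genes, 1 rose, 10 fell and 6 did not pass (camera adjusted p = 0.286), with Ctgf (-1.71) and Amotl2 (-1.74) down, and 7 rose and 6 fell after median centring and 2 rose and 10 fell after quantile normalization. 9 of 13 measured heat shock genes rose, 2 fell and 2 did not pass (adjusted over the list alone, 9 rose and 3 fell). Of 18 measured cholesterol synthesis and uptake genes, 12 rose, 3 fell and 3 did not pass, and for the unfolded protein and integrated stress response 7 rose and 7 fell of 16, where 10 rose and 1 fell after median centring and 8 rose and 3 fell after quantile normalization. 1234 genes were higher and 6490 lower with a median of -0.22 (3557 and 2460 after median centring).

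In p65ko cells Egr1 (from 27.6 to 604 TPM, log2 fold change 4.40), Ier3 (from 78.5 to 1015 TPM, log2 fold change 3.68) and Chac1 (from 76.2 to 369.6 TPM, log2 fold change 2.26) rose, Cxcl1 (from 12.1 to 50.5 TPM, log2 fold change 1.97), Lif (2.27) and Nfkbia (0.73) rose less far, and Ccl2 stayed at 313 ± 10.4 TPM against 312 ± 3.79 TPM (limma, Benjamini-Hochberg adjusted p = 0.951). Irf1 (-1.11) and Csf1 (-0.62) fell, and so did Tnfaip3 (-0.29), but not without treated replicate 1 (adjusted p = 0.101), on the libraries of the comparison alone (0.0975) or after quantile normalization (0.346) or median centring (0.660). 24 of 24 measured immediate early genes rose. Of 13 measured cytokine and chemokine genes, 8 rose, 1 fell and 4 did not pass (adjusted over the list alone, 8 rose and 2 fell). 5 of 20 measured NF-kB target genes rose, 10 fell and 5 did not pass, and 9 rose and 3 fell after median centring and 9 rose and 3 fell after quantile normalization; the median of this last list was -0.079, its mean -0.011 and its camera call upward against the other genes (adjusted p = 0.0364). 1080 genes were higher and 6042 lower with a median of -0.19 (3206 and 2052 after median centring).

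The p65ko and noko responses differed in 502 genes, 287 upward and 215 downward (221 and 339 after median centring), and leaving out any one of the 8 libraries gave 277 to 334. The difference in log2 fold change was -3.87 (SE 0.14) for Cxcl1, -2.97 for Tnfaip3, -2.21 for Cxcl10, -2.06 for Nfkbia, -1.66 for Ccl2, -1.63 for Il6 and -1.46 for Lif, and -0.67 for Fos, -0.60 for Egr1 and -0.50 for Ier3 (limma, Benjamini-Hochberg adjusted p = 1.46e-13 for Cxcl1 and 0.00130 for Ier3). Lower log2 fold changes in p65ko cells were found for 12 of 20 NF-kB target genes (15 adjusted over the list alone; camera, adjusted p = 3.02e-32), 10 of 17 cytokine and chemokine genes (11 adjusted over the list alone; adjusted p = 8.22e-20) and 9 of 24 immediate early genes (14 adjusted over the list alone; adjusted p = 4.48e-11). Upward differences were found for 11 of 18 cholesterol genes (13 adjusted over the list alone) and for Ctgf (0.58), a smaller fall, from -1.71 in noko to -1.13 in p65ko cells. In the control arms siCTR and noko, 1026 genes were higher in both; 269 of them responded less with siPKC, a count that rests on 1 treated library, and 162 less with p65ko, 87 in both against 42.5 expected of independent lists.

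**Figure D4:**
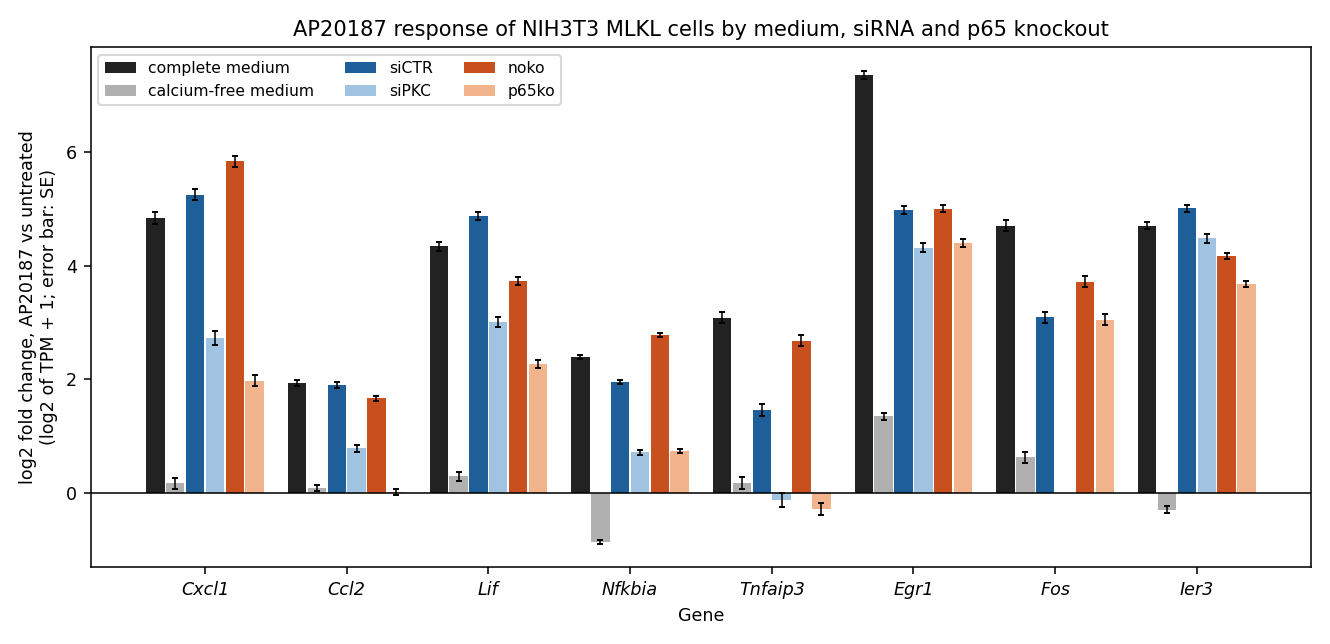
Log2 fold change after AP20187 (bars, with SE as error bars) of 8 genes in NIH3T3 MLKL cells in complete or calcium-free medium, with siCTR or siPKC, and in noko or p65ko cells. Fos has no bar with siPKC because the filter needs 2 libraries at 1 TPM and only the single treated one reached it, and Cxcl1 stands at 4.84 in complete medium, 0.16 without calcium, 2.73 with siPKC and 1.97 in p65ko cells.

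Digitonin for 2 h gave the largest fold changes of the series in the human BxPC3 line. EGR1 (from 11.4 ± 0.225 to 5910.2 ± 73.6 TPM, log2 fold change 8.89, SE 0.03) and ATF3 (from 1.62 ± 0.354 to 1023 ± 27.4 TPM, log2 fold change 8.62, SE 0.11) rose (limma, Benjamini-Hochberg adjusted p = 1.58e-10 for EGR1). With them FOSB (from 14.4 ± 0.0603 to 5375 ± 53.2 TPM, log2 fold change 8.45, SE 0.031), NR4A1 (from 4.64 to 2168 TPM, log2 fold change 8.59), EGR3 (from 0.525 to 675 TPM, log2 fold change 8.79) and FOS (from 24.0 to 3489 TPM, log2 fold change 7.12) were among the largest rises. Of 26 measured immediate early genes, 25 rose and 1 did not pass, with a median of 5.32. 17 of 19 measured ERK feedback genes rose and 2 fell, with DUSP1 (from 12.8 to 1191 TPM, log2 fold change 6.43). Of 15 measured calcium, NFAT and CREB responsive genes, 14 rose and 1 fell, with GEM (7.42). 14 of 20 measured cytokine and chemokine genes rose and 6 fell, among them CXCL8 (4.97), the main human neutrophil chemokine, CXCL1 (3.65) and IL11 (4.73). Of 22 measured NF-kB target genes, 17 rose, 4 fell and 1 did not pass, among them NFKBIA (3.95) and TNFAIP3 (3.57). 12 of 19 measured cholesterol synthesis and uptake genes rose, 3 fell and 4 did not pass, with INSIG1 (4.43). 11 of 16 measured unfolded protein and integrated stress response genes rose, 4 fell and 1 did not pass, with PPP1R15A (4.73). 8 of 15 measured p53 target genes rose, 5 fell and 2 did not pass (camera adjusted p = 0.00139, adjusted p = 0.102 with an estimated correlation), with CDKN1A (3.99). Of 14 measured heat shock genes, 10 rose and 4 fell (camera adjusted p = 0.00087, adjusted p = 0.205 with an estimated correlation), with DNAJB1 (3.33). 7 of 10 measured epithelial marker genes rose, 1 fell and 2 did not pass (camera adjusted p = 0.00208, adjusted p = 0.239 with an estimated correlation), with ELF3 (2.70) and CLDN4 (2.54). Of 20 measured ribosomal protein genes, 16 rose, 1 fell and 3 did not pass (camera adjusted p = 5.99e-06, adjusted p = 0.0972 with an estimated correlation), where 20 rose after median centring and 6 rose and 6 fell after quantile normalization. Among the genes that fell were the metallothionein MT1X (-2.43), ACTB (-1.37), ANKRD1 (-2.02), AJUBA (-1.79) and TXNIP (-1.42). 2 of 19 measured membrane repair and ESCRT genes rose and 17 fell (camera adjusted p = 0.0306, adjusted p = 0.303 with an estimated correlation), such as VPS4A (-1.14) and PDCD6 (-0.94). Of 12 measured metal and oxidative stress genes, 3 rose and 9 fell (camera adjusted p = 0.429). 3 of 14 measured interferon stimulated genes rose, 9 fell and 2 did not pass (adjusted over the list alone, 3 rose and 10 fell, camera adjusted p = 0.610). Of 17 measured SRF and YAP target genes, 6 rose, 10 fell and 1 did not pass (camera adjusted p = 0.703), where 8 rose and 6 fell after median centring and 6 rose and 10 fell after quantile normalization. Of 13566 genes 3193 were higher and 7709 lower with a median of -0.37 (5667 and 4889 after median centring), and genes at least 2-fold higher gained 11.5% of all TPM.

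The same dose raised overlapping groups of genes less far in HT29 cells. GEM (from 1.75 ± 0.0199 to 152 ± 5.92 TPM, log2 fold change 5.80, SE 0.049) and FOSB (from 2.49 ± 0.0861 to 163 ± 0.0854 TPM, log2 fold change 5.55, SE 0.031) rose most (limma, Benjamini-Hochberg adjusted p = 4.3e-09 for FOSB). They were followed by PPP1R15A (from 29.4 to 1047 TPM, log2 fold change 5.11), DUSP1 (from 2.97 to 116 TPM, log2 fold change 4.89), CDKN1A (from 3.41 to 124 TPM, log2 fold change 4.83), ATF3 (from 1.98 to 78.5 TPM, log2 fold change 4.75) and KLF6 (4.51). 22 of 23 measured immediate early genes rose and 1 fell, with EGR1 (2.70). Of 9 measured cytokine and chemokine genes, 6 rose, 1 fell and 2 did not pass, with CXCL8 (2.64) and CCL20 (2.5). 11 of 19 measured NF-kB target genes rose, 3 fell and 5 did not pass, with TNFAIP3 (2.29) up, NFKBIA (0.24) little up and TNFAIP2 (-0.75) down; NFKBIA did not pass without treated replicate 2 (adjusted p = 0.0636). Of 18 measured cholesterol synthesis and uptake genes, 16 rose and 2 did not pass, with INSIG1 (3.32). 8 of 16 measured unfolded protein and integrated stress response genes rose, 1 fell and 7 did not pass. Of 12 measured calcium, NFAT and CREB responsive genes, 9 rose, 2 fell and 1 did not pass. 13 of 19 measured ERK feedback genes rose, 4 fell and 2 did not pass (adjusted over the list alone, 13 rose and 5 fell, camera adjusted p = 5.04e-07, adjusted p = 0.0572 with an estimated correlation). Of 15 measured p53 target genes, 7 rose, 5 fell and 3 did not pass (camera adjusted p = 0.00129, adjusted p = 0.105 with an estimated correlation). 8 of 14 measured heat shock genes rose, 4 fell and 2 did not pass (camera adjusted p = 0.00582, adjusted p = 0.263 with an estimated correlation). Of 14 measured SRF and YAP target genes, 8 rose, 3 fell and 3 did not pass (camera adjusted p = 0.000436, adjusted p = 0.111 with an estimated correlation), with CYR61 (2.39) up and AJUBA (-1.40) down. 6 of 12 measured interferon stimulated genes rose, 1 fell and 5 did not pass (camera adjusted p = 0.00529, adjusted p = 0.0804 with an estimated correlation). Of 10 measured epithelial marker genes, 7 rose, 2 fell and 1 did not pass (camera adjusted p = 0.000451, adjusted p = 0.20 with an estimated correlation). 8 of 19 measured membrane repair and ESCRT genes rose, 6 fell and 5 did not pass (camera adjusted p = 0.0172, adjusted p = 0.266 with an estimated correlation). Of 12 measured metal and oxidative stress genes, 6 rose, 4 fell and 2 did not pass (camera adjusted p = 0.0691). 9 of 20 measured ribosomal protein genes rose and 11 did not pass (camera adjusted p = 3.4e-05, adjusted p = 0.105 with an estimated correlation), where 20 rose after median centring and 2 rose after quantile normalization. Of 12193 genes 2028 were higher and 5364 lower with a median of -0.16 (3620 and 3249 after median centring).

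The digitonin response differed between the lines in 9220 genes, 6259 with a larger and 2961 with a smaller log2 fold change in HT29 than in BxPC3 cells (4218 and 4371 after median centring). The difference, HT29 minus BxPC3, was -7.96 for EGR3, -6.20 for EGR1, -5.29 for FOS, -4.37 for CXCL2, -4.19 for IL11, -3.87 for ATF3, -3.71 for NFKBIA and -2.33 for CXCL8, and 4.15 for DHRS9, 1.98 for ANKRD1 and 1.04 for ACTB, of which ANKRD1 and ACTB had fallen in BxPC3 cells (limma, Benjamini-Hochberg adjusted p = 1.79e-08 for EGR1 and 9.85e-06 for ACTB). Log2 fold changes were lower in HT29 cells for 24 of 26 immediate early genes (camera adjusted p = 2.67e-18). So were those of NF-kB target genes in 16 of 22 (camera adjusted p = 3.16e-06, adjusted p = 0.0756 with an estimated correlation) and cytokine and chemokine genes in 13 of 21 (camera adjusted p = 7.13e-05, adjusted p = 0.0583 with an estimated correlation). In contrast, 18 of 19 membrane repair and ESCRT genes differed upward (camera adjusted p = 7.13e-05, adjusted p = 0.178 with an estimated correlation).

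**Figure D5:**
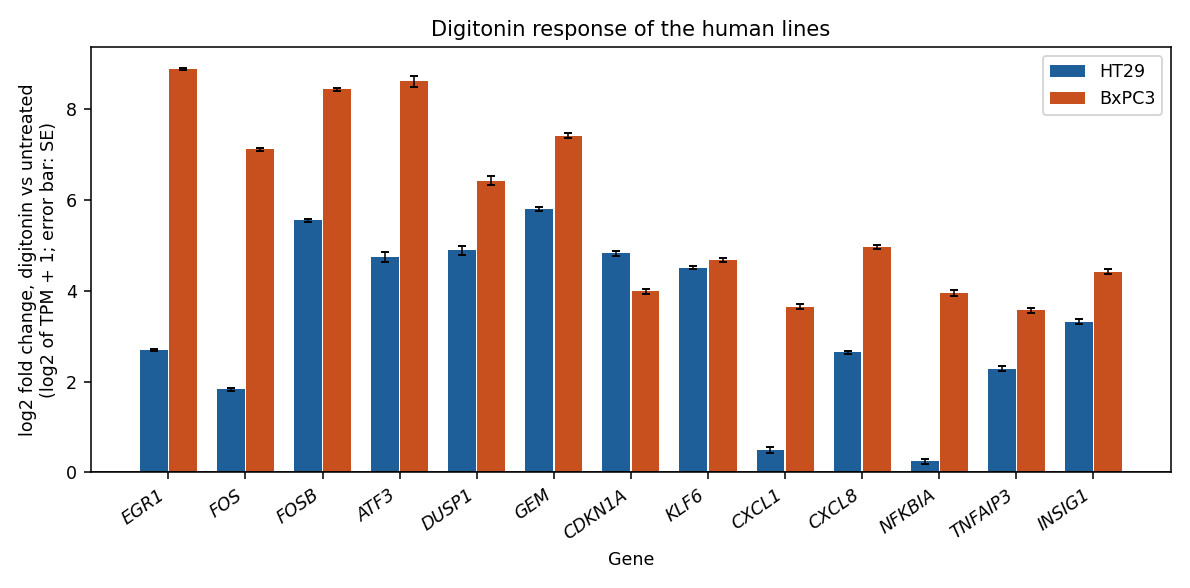
Log2 fold change after digitonin (bars, with SE as error bars) of 13 genes in HT29 (blue) and BxPC3 cells (orange). EGR1 stands at 2.70 and 8.89 and CXCL8 at 2.64 and 4.97.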

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

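The test of a rise of Gsdmd by digitonin and the test of a TPM gain by raised genes, with its spread, were written after the result was seen, and the parental-control and length alternatives were also chosen after the data were seen.

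The LLC libraries of the digitonin arm, labelled as carrying no construct, held 14.8 times the Gsdmd of untreated parental cells before any digitonin was added, which excludes a rise caused by digitonin. If these cells carried the GSDMD construct, other genes should also resemble GSDMD cells, and 82.3% of 674 genes that separate untreated GSDMD from parental cells lay nearer to GSDMD cells, against 42.1% in MLKL cells. The table thus fits cells that may carry the construct. A clone or culture that merely shares history with the GSDMD cells was not tested and stays open, as does a labelling error, so the arm is described by its label.

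The untreated NIH3T3 libraries of the digitonin arm differed from the other untreated groups in a way that follows transcript length (rho = -0.597, against -0.0213 to 0.229 in the other groups) and GC content (rho = 0.368). Both technical explanations, a length and a GC bias of these libraries, fit and could act together. With the length trend removed, 3711 genes were higher and 3783 lower, and 540 of 886 genes stayed at least 2-fold higher. Against parental untreated libraries 275 of 921 did, so the sizes of many rises in this arm remain open; those of Hmgcs1 and Insig1 were 3.08 and 2.88 without the length trend but 1.03 and 1.21 against parental libraries.

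The median log2 fold change lay more than 0.1 below 0 in 8 comparisons. Small RNA and ribosomal RNA rows taking a larger share does not account for it, because at least 93.4% of the shift was kept without them. Transcript length bias does not either in the 6 mouse comparisons among them, where the largest rho was 0.135. A gain of TPM by genes at least 2-fold higher (1.43% to 11.5% of all TPM) may push down the others; with those genes left out and the others rescaled, 67.7% to 86.6% of the shift was kept, and 65.2% in BxPC3 cells without 1 library, under the bound set. At least 65.2% of the shift was thus kept in each of the 8, which argues against this gain as its main source there. A smaller part stays open, as does a true loss of RNA, which was not tested because TPM do not measure it. In NIH3T3 digitonin cells a gain of 5.07% went with a median log2 fold change of 0.02.

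A test of the difference between groups marked 6 more results. AP20187 acted differently on 2446 genes in MLKL and parental NIH3T3 cells. Calcium-free medium altered the AP20187 response of 2593 genes. The responses with siPKC and siCTR differed in 985 genes. Those of p65ko and noko cells differed in 502 genes. The 4OHT response of GSDMD and parental LLC cells differed in 8268 genes. The digitonin response of HT29 and BxPC3 cells differed in 9220 genes.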

How the results depend on the processing

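Median centring, removal of small RNA and ribosomal RNA rows, removal of the length trend and the parental untreated libraries were chosen after seeing the data, and count-based alternatives were not run because the values are TPM. Fitted on the libraries of the comparison alone, which leaves fewer libraries to estimate the spread, limma called 5 genes in parental NIH3T3 cells in place of 35, 2087 in NIH3T3 MLKL cells in place of 3754, 75 in calcium-free medium in place of 673, 27 in parental LLC cells in place of 103, 54 for the siPKC difference in place of 985, 768 for the p65ko difference in place of 502 and 3065 between untreated siPKC and siCTR cells in place of 5259. Leaving out each library in turn, with the lone siPKC library kept and assumed to vary like the other groups, gave 9 to 18 genes in parental NIH3T3 cells, 2500 to 3175 in NIH3T3 MLKL cells, 278 to 388 in calcium-free medium, 12 to 33 in parental LLC cells, 379 to 426 in LLC MLKL cells, 537 to 1160 for the siPKC difference and 277 to 334 for the p65ko difference, again with fewer libraries. With a replicate block the count was 15 in parental NIH3T3 and 49 in parental LLC cells, and no other count moved by more than 1.5 times; samples with the same number correlated by -0.0471 to 0.133 over 15 comparisons, so the numbers do not pair them, and LLC MLKL cells could not be blocked because both treated libraries carry number 2. With an estimated correlation, camera called 2 lists in calcium-free medium, 9 in NIH3T3 GSDMD cells, 1 in parental LLC cells, 6 in HT29 and 7 in BxPC3 cells, 7 for the p65ko difference, 2 for the difference between HT29 and BxPC3 cells, 1 between untreated p65ko and noko cells and 2 between untreated siPKC and siCTR cells, each fewer because correlated members widen the test. Of the 241 genes higher in all 6 mouse comparisons, 12 were at least 2-fold higher, by the stricter threshold, and 281 genes were shared after median centring. Of 344 gene results printed, Gsdmd in LLC GSDMD cells alone reversed, from a log2 fold change of -0.15 (adjusted p = 0.00462) to 0.017 (adjusted p = 0.733) after median centring, and the cause was not tested. Others kept their direction but lost the threshold in 53 refits: 27 that left out a library, 16 on the libraries of the comparison alone, 3 with a replicate block, 3 after median centring, 2 after quantile normalization, 1 with a pseudocount of 0.1 and 1 without small RNA and ribosomal RNA rows. Over all genes of the naming rule 761 refits did so. The single reversal is favourable by choice: among all 1493 gene results of the naming rule, 24 reversed in at least 1 setting (13 times with quantile normalization and 15 with median centring), and most of those genes were passed over for printing.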

Other observations

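The comparison of list members in calcium-free medium was written after the result was seen, and the other tests here before.

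The digitonin arms of both species share a set of raised genes. Of 8207 symbols tested in all 4 arms, 464 were higher in each, against 21.7 expected of independent lists, a ratio of 21.4, and 83 were at least 2-fold higher in all 4. They include EGR1, FOSB, KLF6, ZFP36, DUSP1, LIF, CDKN1A, HMGCS1, INSIG1, PER1 and NR1D1. The ratio fits a common response that may be conserved, with symbols matched by capitals alone. It need not be specific to detergent: EGR1, FOSB and LIF also rose with MLKL and GSDMD in both mouse lines. The LLC arm may carry GSDMD.

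Loss of the AP20187 response with siPKC and in p65ko cells was compared over 1026 genes. The differences correlated across genes with rho = 0.257, between the values set for a shared and a separate effect, so whether PKC and p65 could act on the same genes cannot be told apart by that measure. Pearson r was 0.498, and 87 genes responded less in both, against 42.5 expected of independent lists (Fisher's exact p = 2.72e-16, with genes not independent replicates). Among 183 genes at least 2-fold higher in both control arms, 121 responded less with siPKC, 70 in p65ko cells and 55 in both, against 46.3 expected of independent lists (Fisher's exact p = 0.00617). Every siPKC value here rests on 1 treated library, whose spread is unknown, so these overlaps leave the question open.

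The share of the AP20187 response kept without calcium went both ways within lists, such as -56.4% for Nr4a2 and 18.2% for Egr1 among immediate early genes, and -36.4% for Nfkbia and 16.5% for Nfkbiz among NF-kB target genes. Its median was 1.89% for 22 immediate early genes and 5.60% for 3 NF-kB target genes (permutation p = 0.782), so whether either list might depend less on calcium cannot be told apart.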
